A study of Mus musculus with 5 samples.

How the data were processed

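Spleens of C57/BL6 mice were taken 48 h after intravenous infusion of saline or of live allogeneic (Balbc), live isogeneic (B6), apoptotic allogeneic or apoptotic isogeneic splenic cells. Per the labels' protocols, spleens were digested with collagenase D and DNAse I, enriched magnetically for CD45+ cells and for DCs apart from each other, and mixed again in equal parts. Libraries were made with the single cell 3' v3.1 kit of 10x Genomics, per the labels' protocols. The number of mice per library is not given in the sources used here. The deposited values are UMI counts per gene and barcode, whole numbers of at least 1, made with Cell Ranger 4.0 on mm10, per the file headers and per the labels. They carried no normalization. Files of 4 libraries held every barcode of the kit (6794880), and that of the apoptotic allogeneic library held 2491 barcodes with at least 500 UMIs each. Each feature table held 32285 genes with Ensembl identifiers, and gene positions were taken from a GRCm38 (mm10) annotation matched on these.

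The same filter was applied to all 5 libraries: at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Barcodes with at least 1000 UMIs numbered 3055 (saline), 1292 (live allogeneic), 4057 (live isogeneic), 2232 (apoptotic allogeneic) and 6577 (apoptotic isogeneic). The gene minimum left 3012, 1248, 3903, 2211 and 6524 of them and the mitochondrial limit 2902, 1186, 3685, 2118 and 6380. Doublets were called by Scrublet within scanpy per library, with an expected rate of 0.8% per 1000 cells and the tool's own threshold. It removed 8, 1, 5, 4 and 117 cells, which is under 0.3% in each library but the apoptotic isogeneic one (1.83%), below the rate given to the tool, so that an unknown number of doublets remained. In all, 16136 cells were kept.

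Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1 gave 30 clusters. Clusters were named "like" a cell type from markers of 17 classes. A marker counted when its log2 ratio to the other cells was at least 1 and at least 10% of the cluster's cells had a UMI. A name needed at least 3 such markers and 25% of the class's markers, and leading genes that did not go against it. Clusters 20 (led by Coch, Dcn and Cxcl12), 26 (plasma cell genes with more B cell markers among its top 10 genes) and 29 stayed unnamed. A class was compared between libraries only with at least 30 cells and 50000 UMIs in each, so that mature DC-like cells, 23 in the live allogeneic library, were compared for apoptotic cells alone.

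For each class and library the UMIs of all cells were summed and scaled to CPM. Log2 ratios carry a pseudocount of 10 CPM, while folds are ratios of CPM without one, with exact conditional Poisson intervals at 95%. Shares of cells have exact Clopper-Pearson intervals. With 1 library per group no test was run across genes. Intervals cover counting error only. Where a sum was 0, a bound was computed against a floor of 3 counts in the class sum.

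The 12 gene lists compared were type I interferon response, interferon-gamma response, DC maturation and costimulation, NF-kappaB targets, inflammatory cytokines and chemokines, MHC class II presentation, MHC class I presentation, apoptotic cell uptake and cholesterol efflux, paired immunoglobulin-like receptors and SIRP-CD47, cell cycle, lymphocyte activation and cytotoxicity, and dissociation and heat stress. The lists share some genes. Another list held strain and sex markers. A list's value is the median log2 ratio over members with at least 20 UMIs in the 2 sums, with an interval from 400 Poisson redraws. Its percentile was taken among 10000 random lists of the same size matched in 20 bins of expression, as a description of these libraries. Members count as higher or lower at 1.5-fold, a rule of size without a test. The gene spread is the 90th percentile of absolute log2 ratios after each class sum was thinned to 374151 UMIs, over 50 thinnings, set beside 100 Poisson draws from 1 shared profile.

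Named genes were those of the highest and the lowest log2 ratio: 10 each in cDC2-like cells for both allogeneic to isogeneic pairs, 5 each for both allogeneic libraries against saline, 5 each in cDC1-like and pDC-like cells and 3 each in other classes. They needed at least 50 UMIs in the 2 sums and a UMI in at least 10% of the cells of 1 library, so that a fold can rest on few cells. Immunoglobulin, T cell receptor, haemoglobin, mitochondrial, ribosomal protein and sex genes were left out, as were genes under 0.1 of their CPM in the class highest for them, as possible free RNA. Classes with fewer than 10 cells or 50000 UMIs were not counted as the highest class. List examples were the 4 members with the most UMIs among those past 1.5-fold.

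Scripts for ratios, lists and spread were tested on simulated data for cDC2-like cells, live allogeneic against live isogeneic, over 9046 genes, with 200 genes changed by known folds. Of genes made with a fold of 1.5, 2, 4 and 8 (50 each), 48%, 98%, 100% and 100% passed 1.5-fold, as did 12.6% of the 8846 unchanged ones. The true fold lay in the interval for 94% to 100% of them. Counts were drawn as Poisson from 1 profile, as the intervals assume. Coverage here and for the lists was thus largely set in advance, and differences between cells or animals were not simulated. For 40 unchanged lists of 38 genes the true median lay in the interval 39 times, and 37 had a percentile from 2.5 to 97.5. For 40 doubled lists it did 39 times. The spread of unchanged genes was 0.61 against 0.61 for Poisson counts, and 0.65 against 0.61 with the 200 changed genes. The test was written after the ratios had first been computed on the real counts.

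Groups, lists, markers, filters, the named-gene rule and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Alternatives changed 1 choice at a time: the UMI minimum per barcode, the mitochondrial limit, doublet removal, TMM factors of edgeR or median-centred ratios in place of the total, the pseudocount, the UMI minimum per gene, the mean CPM per cell, cells thinned to 1000 UMIs, free RNA subtracted, clustering resolution and centring per library. The free RNA alternative scaled the library profile on B cell genes (Cd79a, Cd79b, Ighd and Ms4a1) and was therefore not used for B cell-like cells. Barcodes under 100 UMIs served as a profile of free RNA in the 4 libraries that hold them. The strain marker genes H2-Ea and H2-Ea-ps have no entry in the feature tables and were not analysed here.

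Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for the TMM alternative.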

Results

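Single-cell RNA sequencing was used to measure gene expression in spleen cells of C57/BL6 mice 48 h after an intravenous infusion. The 5 libraries were 1 each of saline and of live allogeneic, live isogeneic, apoptotic allogeneic and apoptotic isogeneic cells. The infused cells were splenic cells, per the labels. Allogeneic cells came from Balbc donors and isogeneic cells from B6 donors, so that only the former carried foreign antigen. The digested spleens had been enriched separately for CD45-positive cells and for dendritic cells (DCs), and the 2 fractions had been mixed again in equal parts. Total unique molecular identifiers (UMIs) were 18125660 in the saline library, 12742889 in the live allogeneic one, 32641733 in the live isogeneic one, 16049698 in the apoptotic allogeneic one and 24206160 in the apoptotic isogeneic one. Cells kept numbered 2894, 1185, 3680, 2114 and 6263 in that order, with medians of 3420.5, 4974, 3880, 4465.5 and 2267 UMIs per cell. Each group had 1 library, so no difference given here has a replicate check, and the intervals cover counting error only.

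Conventional DCs of type 2 (cDC2), the CD4 T cell-priming DCs the series title is about, were found as 2 clusters named cDC2-like from fixed markers. Cluster 1 was led by Cd209a, Ms4a6c and S100a4, and cluster 12 by Ffar2, Adam23 and Cyp4f16. Ms4a6c and S100a4 are also among the fixed markers of classical monocytes. Cells of cDC2-like type made up 44.5% (95% Clopper-Pearson interval 41.3 to 47.7) of the 965 DCs in the saline library, 43.6% (37.6 to 49.8) of 266 in the live allogeneic one, 40.1% (36.8 to 43.5) of 858 in the live isogeneic one, 47.2% (43.5 to 51.0) of 722 in the apoptotic allogeneic one and 50.2% (46.8 to 53.6) of 860 in the apoptotic isogeneic one. Of all cells they were 14.8%, 9.79%, 9.35%, 16.1% and 6.90% in the same order, shares that the magnetic enrichment partly sets. With clustering at a resolution of 2, where cDC2-like meant fewer cells, the shares of DCs were 16.6%, 23.5%, 16.7%, 18.9% and 22.2%, in another order of libraries. Cross-presenting type 1 cells (cDC1-like) were 30.8%, 33.1%, 34.5%, 32.0% and 25.5% of the DCs, and plasmacytoid DC-like (pDC-like) cells 12.9%, 14.7%, 13.9%, 9.42% and 14.2%. Mature DC-like cells, led by Fscn1 and Gadd45b, were 11.9%, 8.65%, 11.5%, 11.4% and 10.1%.

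The first question was whether live allogeneic cells act on the cDC2 transcriptome beyond live isogeneic cells. Interferon-stimulated genes stood highest in the 116 cDC2-like cells of the live allogeneic library against the 344 of the live isogeneic one. Cxcl9, a chemokine that draws CXCR3-bearing lymphocytes, was at 612.5 against 69.0 CPM (UMIs of a gene scaled to an equal total per library), 8.87-fold (95% Poisson interval 7.52 to 10.5), although 14.7% of the live allogeneic cDC2-like cells held all of its UMIs there, so that few cells carry this fold. Isg15, a ubiquitin-like modifier, was at 537.2 against 84.8 CPM, and Irf7, a transcription factor of the interferon response, at 292.4 against 49.9 CPM. With each cell thinned to 1000 UMIs, 62.1% (52.6 to 70.9) of live allogeneic and 26.7% (22.1 to 31.8) of live isogeneic cDC2-like cells held at least 3 UMIs of type I interferon genes, against 27.3%, 19.9% and 27.1% in the saline, apoptotic allogeneic and apoptotic isogeneic libraries. Before thinning these shares were 98.3%, 93.0%, 86.7%, 88.9% and 82.6%, at medians of 9019.5, 7457.5, 5355, 6850 and 4022 UMIs per cell. Gm42418, which overlaps ribosomal RNA sequence, stood lowest, at 12270 against 57250 CPM. It was at 13740, 18180 and 14100 CPM in the saline, apoptotic allogeneic and apoptotic isogeneic libraries, so that the live isogeneic library stood apart from the other 4.

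Of the 10 genes farthest up, 8 are known interferon-stimulated genes. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818 in mm10) was 6.34-fold (5.43 to 7.42) higher and Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) 5.87-fold (4.78 to 7.24). Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 at 92321347 to 92328079, close to Cxcl10 (ENSMUSG00000034855, 92346638 to 92348889), which encodes another CXCR3 ligand and was 5.34-fold (4.25 to 6.74) higher, with UMIs in 14.7% of the live allogeneic cells. Ifi204 and Ifi211, DNA-sensing family genes that lie near each other on chromosome 1 and resemble each other in sequence, were 7.62-fold (5.43 to 10.9) and 8.18-fold (5.49 to 12.5) higher, so that reads of one can be counted in the other. The nucleic acid sensor Zbp1 was 5.15-fold (4.05 to 6.59) higher and Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), a blocker of viral RNA translation, 5.28-fold (4.02 to 7.01). The other genes of the 10 were Lgals1, which encodes galectin-1 and stood 4.50-fold (3.88 to 5.23) higher, and Gm20186, an unannotated transcript, at 5.01-fold.

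Some of the 10 genes farthest down were as low in other cell classes. Gm42418 (chromosome 17, 39846958 to 39848788) was 0.214-fold (0.211 to 0.218) and AY036118, which overlaps it, so that reads of the pair can be shared, 0.395-fold. Lars2, a mitochondrial tRNA ligase gene, was 0.232-fold, at 1489 CPM in the live isogeneic library against 449.8, 565.1 and 390.2 CPM in the saline, apoptotic allogeneic and apoptotic isogeneic ones, and Gm10076 was 0.320-fold. Gm42418 ranged from 0.158-fold in erythroid-like to 0.305-fold in cDC1-like cells, over the 7 classes in which it was named for this pair of libraries. With saline as the reference, AY036118 was higher in the live allogeneic library (log2 ratio 0.095), as it was with the apoptotic isogeneic library as the reference (0.29). Zfp36, which encodes an mRNA-destabilizing protein, was at 215.4 against 509.7 CPM, 0.423-fold (0.368 to 0.484), but stood higher than in the saline (0.43) and the apoptotic isogeneic library (0.31). Gm10076 was likewise higher than in the apoptotic isogeneic library (1.22). Zfp36l1, a relative of Zfp36, was 0.421-fold, the transcription factor genes Ehf and Sox4 0.312-fold and 0.359-fold, the scaffold gene Mpp7 0.353-fold and the cell death gene Pmaip1 0.429-fold.

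The type I interferon list had 38 measured genes in cDC2-like cells, of which 33 were at least 1.5-fold higher with live allogeneic cells, 0 lower and 5 between. Its median log2 ratio was 1.10 (1.005 to 1.215), at the 100th percentile of random lists matched on expression. The list also held Ifi209 and Trim30a at 1.81-fold and 1.79-fold. Of 23 measured interferon-gamma response genes, 17 were higher and 0 lower, with a median of 1.09 (0.74 to 1.25). Fgl2 and Serpina3g, at 1.67-fold and 1.60-fold, were among them beside Cxcl9 and Cxcl10. Major histocompatibility complex (MHC) class I presentation genes had a median of 0.39 (0.29 to 0.55), with 11 of 23 higher and 0 lower, including the proteasome genes Psmb8, Psmb9, Psme1 and Psme2 at 1.69-fold, 1.86-fold, 1.66-fold and 2.08-fold. Inflammatory cytokine genes had a median of 0.60 (0.28 to 0.81), with 6 of 11 higher. Ccl3 and Cxcl16, both chemokine genes, were 2.35-fold and 1.94-fold higher.

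Maturation and costimulation genes were not shifted as a list, with a median of 0.035 (-0.060 to 0.17) and 5 of 26 higher, 1 lower and 20 between. Within it Cd40, a receptor for T cell help, was 2.74-fold and Ccr7, the receptor for migration to T cell zones, 2.30-fold higher, while the survival gene Birc3 was 0.559-fold. The 2 clusters went opposite ways here: the maturation median was 0.59 in cluster 1 (46 against 101 cells) and -0.33 in cluster 12 (70 against 243 cells), whereas the type I interferon median was 1.24 and 0.91. NF-kappaB target genes had a median of -0.005 (-0.12 to 0.19), with Sod2 at 1.70-fold and Rel at 0.628-fold and 17 of 25 between. This list too went opposite ways, at 0.27 (0.097 to 0.45) in cluster 1 and -0.23 (-0.29 to -0.002) in cluster 12. MHC class II genes had a median of -0.11 (-0.18 to -0.018), with 12 of 14 between, H2-DMb1 at 1.71-fold and H2-Ob at 0.664-fold. Their median was -0.31 (-0.48 to -0.26) in cluster 1 and 0.079 (-0.003 to 0.15) in cluster 12.

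Cell cycle genes were higher with live allogeneic cells, at a median of 0.54 (0.36 to 0.61), with 17 of 31 higher and 2 lower. Stmn1 and Pclaf were 1.91-fold and 1.97-fold and the proliferation gene Mki67 1.75-fold. Apoptotic cell uptake and cholesterol efflux genes had a median of -0.32 (-0.49 to -0.086), with 6 of 17 lower and 3 higher, among them Nr4a1, an early response gene, at 0.476-fold and Apoe, a lipid carrier gene, at 0.653-fold. Paired immunoglobulin-like receptor and SIRP-CD47 genes had a median of 0.14 (-0.061 to 0.27). Within this list, Sirpa, the cDC2 marker that binds CD47, was nonetheless 0.622-fold, the kinase gene Syk 0.610-fold and the phosphatase gene Ptpn11 0.645-fold. Lymphocyte activation genes had a median of 0.099 (-0.039 to 0.26), with 7 of 19 higher and 3 lower. Dissociation and heat stress genes had a median of -0.31 (-0.40 to -0.15), with 9 of 23 lower, Junb at 0.608-fold and Btg2 at 0.626-fold. Against saline, this list was at 0.33 (0.24 to 0.48) in the live isogeneic and 0.26 (0.090 to 0.32) in the live allogeneic library.

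Markers of other cell types were measured in the same cells. Classical monocyte markers had a median of 0.87 (0.78 to 0.99), with 7 of 10 higher, and Lyz2, the myeloid lysozyme gene, at 1754 against 508.2 CPM. They were 0.83 in cluster 1 and 0.25 in cluster 12. Cluster 1, led in part by such markers, held 46 of 116 live allogeneic and 101 of 344 live isogeneic cDC2-like cells. Cells named classical monocyte-like were 3 in the live allogeneic and 44 in the live isogeneic library. Whether monocytes entered the cDC2-like class was not tested. Markers of cDC2 themselves had a median of -0.32 (-0.44 to -0.23), with 5 of 18 lower, including the lectin gene Cd209a at 0.577-fold and the integrin gene Itgam at 0.580-fold. Macrophage markers had a median of 0.42, cDC1 markers 0.44, pDC markers 0.39, T cell markers 0.34, mature DC markers 0.12, natural killer cell markers -0.11, non-classical monocyte markers -0.23, B cell markers -0.37, progenitor markers -0.40 and erythroid markers -1.15. The B cell marker Igkc was 0.337-fold, and erythroid markers stood 1.17 above saline in the live isogeneic library.

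**Figure D1:**
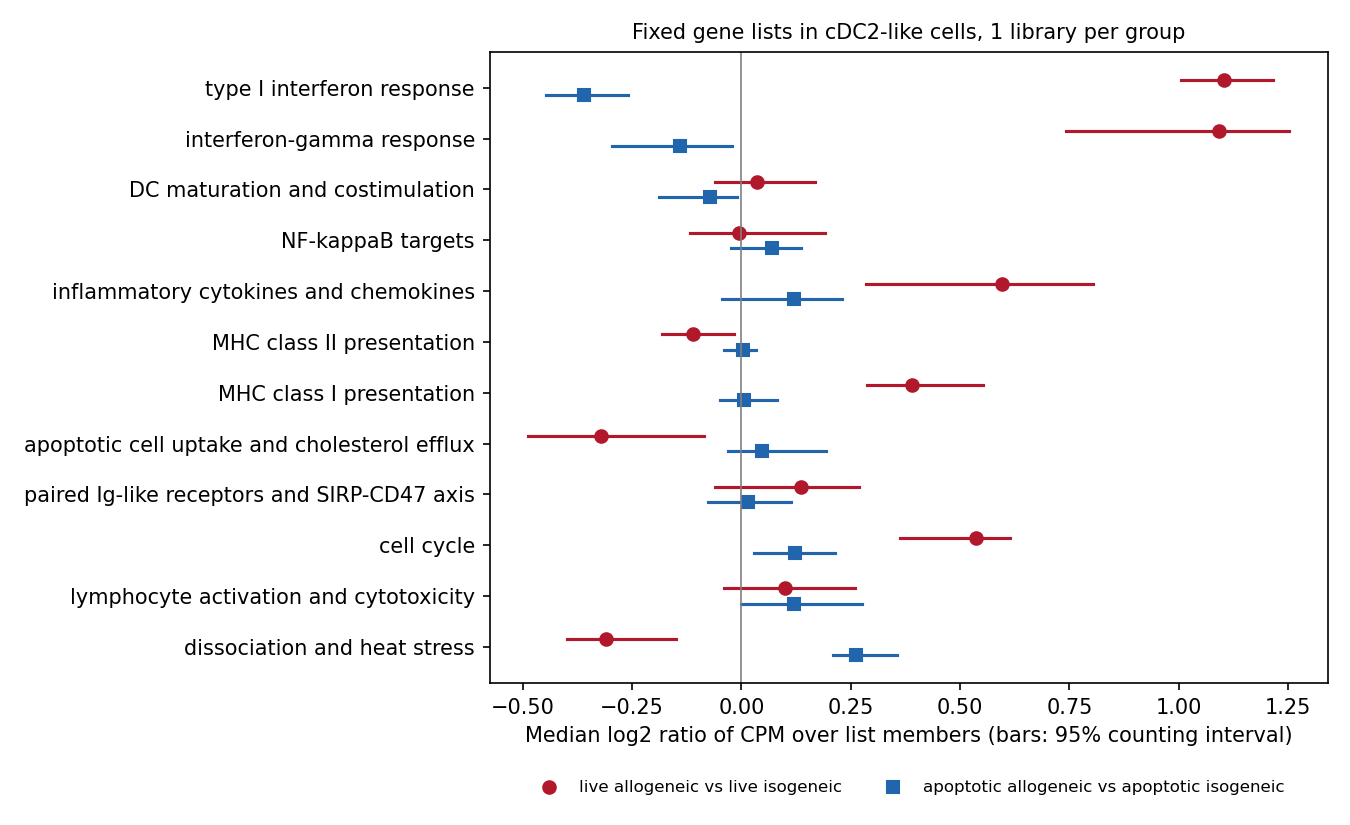
Median log2 ratio of CPM (horizontal axis) over the measured members of 12 gene lists (vertical axis) in cDC2-like cells, for live allogeneic against live isogeneic (circles) and apoptotic allogeneic against apoptotic isogeneic cells (squares), with bars giving 95% counting intervals. The type I interferon list lies at 1.10 for live and -0.36 for apoptotic cells.

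The second question was the same for apoptotic cells, in 341 cDC2-like cells of the allogeneic and 432 of the isogeneic library. A pair of heat shock genes stood highest, and 3 of the 10 genes farthest down are known interferon-stimulated genes. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), which encodes an inducible chaperone, was at 104.4 against 31.4 CPM, 3.32-fold (2.49 to 4.50). Its near-identical neighbour Hspa1a, with which it can share reads, was 2.81-fold (2.12 to 3.75) higher. Ifit3 was at 16.4 against 39.0 CPM, 0.421-fold (0.277 to 0.629), and Ifi27l2a, another interferon-stimulated gene, at 364.8 against 581.0 CPM, 0.628-fold (0.573 to 0.687).

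Further genes named as high were Atf3, a stress-response transcription factor gene, at 2.05-fold (1.47 to 2.90), the RNA polymerase subunit gene Polr2l at 2.37-fold, the proteasome activator copy Psme2b at 2.27-fold, the ribosome quality control gene Zfp598 at 2.94-fold, Zfp971 at 3.18-fold, the myristoylation gene Nmt2 at 2.23-fold, Gm10076 at 1.97-fold and the non-coding Dleu2 at 1.84-fold. Dhx58, which encodes a viral RNA receptor, was 0.522-fold (0.339 to 0.797) and Siglece, an inhibitory receptor gene, 0.557-fold. The DNA repair genes Paxx and Faap20 were 0.491-fold and 0.560-fold, Wdr89 0.574-fold, the kinase gene Prkd2 0.523-fold, the mitochondrial peptidase gene Immp1l 0.576-fold and Gm5617 0.571-fold. With saline as the reference, Gm10076 (-0.66) and Psme2b (-0.28) were lower and Wdr89 (0.21) and Ifi27l2a (0.044) higher in the apoptotic allogeneic library, opposite to the above.

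Type I interferon genes had a median of -0.36 (-0.45 to -0.26), with 15 of 37 lower, 0 higher and 22 between, at the 0th percentile of random lists. Isg15 was 0.647-fold, Irf7 0.631-fold and Sp100 0.656-fold. The interferon-gamma list had a median of -0.14 (-0.30 to -0.021), with 6 of 20 lower and 1 higher, including Cxcl9 at 0.482-fold, Cxcl10 at 0.524-fold and the GTPase gene Igtp at 0.621-fold. This median was -0.49 in cluster 1 and 0.096 in cluster 12. Maturation genes had a median of -0.072 (-0.19 to -0.011), with 19 of 23 between, the chemokine gene Ccl5 at 580.2 against 1065 CPM and Ccr7 at 0.447-fold. Dissociation and heat stress genes had a median of 0.26 (0.21 to 0.36), with 5 of 23 higher and 1 lower, the immediate early genes Fos and Fosb at 1.60-fold and 1.61-fold among them.

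The other lists lay close to 0 in this pair. The median was 0.003 for MHC class II and 0.006 for MHC class I genes, with all 14 and all 23 measured genes between. It was 0.069 for NF-kappaB targets, 0.12 (-0.044 to 0.23) for cytokines, where the interleukin 1 antagonist gene Il1rn was 0.295-fold, 0.046 for apoptotic cell uptake, 0.016 for paired immunoglobulin-like receptors, 0.12 for lymphocyte activation and 0.12 (0.028 to 0.22) for the cell cycle. For some lists the clusters went opposite ways. NF-kappaB targets were at -0.16 (-0.31 to -0.023) in cluster 1 and 0.15 (0.05 to 0.24) in cluster 12. MHC class II genes were at 0.11 (0.022 to 0.15) and -0.058 (-0.09 to -0.012) in these clusters. B cell markers had a median of -0.88 (-1.09 to -0.66), with 11 of 14 lower, and T cell markers -0.59 (-0.77 to -0.37), with 7 of 10 lower, such as Ms4a1 at 0.466-fold and Trbc2 at 0.291-fold. Markers of cDC2 (0.012), cDC1 (0.028), pDC (0.001), non-classical monocytes (0.042), macrophages (0.11), classical monocytes (-0.098) and mature DCs (-0.14) differed less.

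Against saline, interferon genes again set the live allogeneic library apart in cDC2-like cells. The type I list had a median of 1.15 (1.02 to 1.24) there, with 34 of 38 higher, against 0.002 (-0.099 to 0.061) in the live isogeneic, -0.30 (-0.37 to -0.19) in the apoptotic allogeneic and 0.085 (0.005 to 0.18) in the apoptotic isogeneic library. The last of these was -0.008 after each cell was thinned to 1000 UMIs. The interferon-gamma list was at 1.19 (1.001 to 1.42), 0.12 (0.009 to 0.28), -0.14 (-0.26 to 0.011) and 0.086 (-0.10 to 0.22) in the same order, the live isogeneic value being -0.045 after thinning. Maturation medians were -0.031, -0.040, -0.15 and -0.051. Cell cycle medians were 0.93 (24 of 28 higher), 0.25, -0.035 and -0.20, and MHC class I medians 0.62 (15 of 23 higher), 0.19, -0.013 and -0.044. The 4 ratios share 1 saline library.

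Among single genes, Cxcl9 was 31.0-fold (23.01 to 42.8) above saline with live allogeneic cells, at 612.5 against 19.7 CPM, Cxcl10 14.1-fold (9.93 to 20.4), Ifi204 13.3-fold (8.56 to 21.7), Ifi211 10.6-fold (6.70 to 17.6) and the GTPase gene Gbp2 8.50-fold (5.75 to 12.9). Sox4 was 0.253-fold, the actin-capping gene Tmod2 0.175-fold (0.0735 to 0.360), Pbxip1 0.355-fold and the transcription factor gene Zbtb20 0.360-fold. Ptchd1 had 1 UMI with live allogeneic cells and 55 with saline, 0.0367-fold (0.000912 to 0.213). With clustering at a resolution of 2, where cDC2-like meant only the cluster led by Cd209a, Tmod2 had a log2 ratio of 0.029. With apoptotic allogeneic cells, Hspa1b was 3.08-fold (2.38 to 4.02) above saline, Hspa1a 2.62-fold, Atf3 2.54-fold, Lyz2 2.34-fold and the iron-sulfur assembly gene Bola2 1.92-fold. Ifit3 was 0.472-fold (0.314 to 0.700), Zfp329 0.478-fold, Anks1 0.454-fold, the small RNA-binding gene Ago1 0.423-fold and the topoisomerase gene Top3b 0.518-fold.

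Next, cDC1-like and pDC-like cells were compared in the same way, since the series title calls the effect selective for cDC2. In cDC1-like cells, 12 of 24 type I interferon genes were higher with live allogeneic than live isogeneic cells and 0 lower, at a median of 0.35 (0.27 to 0.52), with Irf7 at 1.89-fold. Interferon-gamma genes had a median of 0.24 (0.045 to 0.36), with 8 of 20 higher and 3 lower: Iigp1, a GTPase gene of host defence, was 4.79-fold (3.04 to 7.70) and Ly6a 4.12-fold, but Cxcl10 0.278-fold. Maturation genes were lower, at -0.28 (-0.39 to -0.082), with 9 of 21 lower and 2 higher, and Apol7c, a lipoprotein family gene of mature DCs, at 311.3 against 837.4 CPM. Cluster 18, which Apol7c helped to set apart, held 27 of 88 and 128 of 296 cDC1-like cells. Cell cycle genes were at 0.49 (0.40 to 0.62), with 17 of 34 higher, including Pclaf at 2.37-fold and Stmn1 at 1.98-fold. The named genes Ube2c, Cenpf and Aspm, which act in mitosis, were 3.41-fold, 3.03-fold and 3.90-fold. A cluster led in part by cycle genes, cluster 23, held 21 of 88 and 22 of 296 cDC1-like cells. Uptake genes were at -0.36, dissociation genes at -0.22 and B cell markers at -1.11. Mefv, the pyrin gene, had 3 UMIs against 111, 0.0658-fold (0.0134 to 0.197), and the nuclear receptor gene Nr4a2 was 0.194-fold. Gm11808 was 3.86-fold and Gm10076, Lars2 and Gm42418 were 0.266-fold, 0.268-fold and 0.305-fold.

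With apoptotic cells, type I interferon genes in cDC1-like cells were at -0.16 (-0.22 to -0.002), with 23 of 25 between, and cell cycle genes at 0.25 (0.14 to 0.36), with 9 of 34 higher. NF-kappaB targets were at 0.15, dissociation genes at 0.11, lymphocyte activation genes at -0.29 and B cell markers at -0.74. The histone genes Hist1h2ap and Hist1h2ab were 6.93-fold (4.27 to 11.9), from UMIs in 17.8% of the apoptotic allogeneic cells, and 2.81-fold, near-identical copies of a family that can share reads, and Hist1h2ab had a log2 ratio of -0.51 after each cell was thinned to 1000 UMIs. Hspa1a was 3.90-fold (2.57 to 6.16), Polr2l 2.32-fold and Gm43305 2.31-fold. Cirbp, a cold-inducible RNA-binding gene, was 0.501-fold, Polr2h 0.461-fold, Ftl1-ps1 0.457-fold, Gm20559 0.435-fold and Zfp36l2 0.518-fold.

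Among pDC-like cells, 39 in the live allogeneic and 119 in the live isogeneic library, 15 of 25 type I interferon genes were higher with live allogeneic cells and 0 lower, at a median of 0.62 (0.39 to 0.74). Interferon-gamma genes were at 0.50 (7 of 14 higher, 2 lower), NF-kappaB targets at -0.38 (8 of 20 lower, 0 higher), cell cycle genes at -0.86 (8 of 11 lower), lymphocyte activation genes at -0.81, dissociation genes at -0.48 and T cell markers at -1.10. Cd8a, a coreceptor gene also found in DCs, was 2.89-fold (2.22 to 3.79), the lipid transfer gene Pltp 2.52-fold (2.20 to 2.89), Gm11808 4.43-fold, Gm20186 4.13-fold and 2310039H08Rik 3.22-fold. The lectin genes Cd209a and Cd209d were 0.177-fold (0.0922 to 0.311) and 0.273-fold, the centrosome gene Fgfr1op 0.179-fold, Lars2 0.242-fold and Gm42418 0.296-fold. With apoptotic cells, type I interferon genes were at 0.27 (0.11 to 0.42), opposite in sign to cDC2-like cells, maturation genes at 0.40 (4 of 8 higher), NF-kappaB targets at 0.35 and dissociation genes at 0.29. Klf4, a transcription factor gene, was 5.23-fold (2.51 to 12.2), Mob3a 3.30-fold, Zcchc9 2.66-fold, Sh3gl1 2.38-fold and the histone methyltransferase gene Ezh2 2.35-fold. Ccl4 was 0.317-fold and the chemokine receptor gene Ccr2 0.339-fold, with 5830428M24Rik, 2310009A05Rik and Sgpl1 between 0.436-fold and 0.454-fold.

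The spread of log2 ratios over genes was taken at an equal 374151 UMIs per class and library. Its 90th percentile was 0.83 in cDC2-like cells for live allogeneic against live isogeneic cells, 0.74 in cDC1-like and 0.78 in pDC-like cells. It was 0.74, 0.75 and 0.74 for live isogeneic cells against saline, and 0.64, 0.65 and 0.65 for apoptotic allogeneic against apoptotic isogeneic cells, where Poisson counts of 1 shared profile gave 0.61, 0.61 and 0.605. Any difference between a pair of animals or libraries adds to this spread, so that it neither ranks the classes nor shows a difference particular to allogeneic cells. Across 6573 genes in cDC2-like cells, the live and the apoptotic allogeneic to isogeneic ratios had a Pearson correlation of -0.10 and a Spearman correlation of -0.084, with 46.6% of genes on the same side of 0. This share was 46.5% in cDC1-like, 48.0% in pDC-like, 46.3% in B cell-like and 46.0% in T cell-like cells. Pearson correlations there were -0.025, -0.035, -0.092 and 0.027. The share is thus not particular to cDC2-like cells. The 10 genes highest in live allogeneic cDC2-like cells were all below 0 in the apoptotic pair, at a median of -0.58.

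Interferon genes were also higher in B cell-like and T cell-like cells of the live allogeneic library. In B cell-like cells, where the median of all genes was -0.15, type I interferon genes were at 1.12 (0.96 to 1.17), with 31 of 36 higher and 0 lower, and interferon-gamma genes at 1.19, with 19 of 24 higher. Ifit3 was 7.0-fold (5.48 to 9.02) and Isg15 5.71-fold (4.75 to 6.91), while cell cycle genes were at -0.50 and Zfp36l2, an mRNA decay gene, 0.211-fold. In B cell-like cells the type I median ranged from 0.465 to 1.47 over the alternatives run and the interferon-gamma median from 0.595 to 1.81. The log2 ratio of Ifit3, 2.22 here, ranged from 0.911 to 2.73. Cluster 9, led by interferon-stimulated genes such as Ifit3, held most B cell-like cells of any cluster in the live allogeneic library and cluster 8, led by Fcer2a, in the live isogeneic one. T cell-like cells had type I interferon genes at 0.76 (0.67 to 0.88), with 27 of 35 higher and 1 lower. Cluster 7, led by Cd8b1, held most of them of any cluster in the live allogeneic library (55 of 148) and cluster 6 in the live isogeneic one (223 of 544). Their cell cycle genes were at 1.86 (1.73 to 2.01), with 34 of 34 higher, but at -0.089 within cluster 6, -0.60 within cluster 7, 1.19 within cluster 14 and 0.75 within cluster 15, which were formed in part on cycle genes. Pclaf, a replication factor gene, was at 20.6-fold (15.4 to 27.9), and the histone genes Hist1h1b and Hist1h2ae, of a family that can share reads, were at 14.7-fold and 13.9-fold. UMIs of these genes were in 13.5%, 12.2% and 17.6% of the 148 cells, and with clustering at a resolution of 0.5 the log2 ratio was 0.62 for Hist1h1b and 1.065 for Hist1h2ae. Over the alternatives run, the median of the cycle list was between 0.715 and 2.37, and it was as low as 0.564 in 20 further thinnings of each cell to 1000 UMIs. The inflammatory brake gene Tnfaip3 was 0.201-fold and B cell markers in T cell-like cells were at -1.51.

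In natural killer (NK) cell-like cells, 35 against 132, no difference in type I interferon genes was detectable at this depth with live allogeneic cells, at -0.10 (-0.39 to 0.15), while 27 of 27 cell cycle genes were higher, at 1.54 (1.21 to 1.81), with Hist1h1b at 8.38-fold from UMIs in 20% of the 35 cells, a log2 ratio of 2.93 that was between 0.991 and 3.31 over the alternatives run. Macrophage-like cells, 37 against 63, had cell cycle genes at 1.43, with 13 of 14 higher, and Stmn1 at 26.3-fold (8.65 to 130.5) from 3 UMIs in the live isogeneic library. Their type I interferon genes were at 0.33 (0.16 to 0.63), but at -0.24 after subtraction of free RNA. Ly6d and Ms4a1, which are B cell genes, were at least 20.97-fold and at least 17.3-fold lower there, against a floor of 3 counts in the class sum, with Poisson upper limits of 0.0603-fold and 0.0736-fold. The log2 ratio of Ly6d was -0.534 after subtraction of free RNA. Erythroid-like cells had MHC class I genes at 0.57, with 14 of 23 higher, H2-Q7, which has close paralogs, at 3.90-fold (3.33 to 4.57), the interferon-induced Rtp4 at 4.95-fold and type I interferon genes at 0.62 (0.47 to 0.69). These were 54 live allogeneic cells at a median of 41387.5 UMIs against 326 live isogeneic cells at 3955. Cells of unlike kind may thus be compared here.

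For apoptotic cells, type I interferon genes were at -0.17 in B cell-like, -0.085 in T cell-like, -0.19 (-0.47 to 0.045) in natural killer cell-like and 0.11 (-0.098 to 0.32) in macrophage-like cells. Most B cell-like cells of any cluster were in cluster 8 in the apoptotic allogeneic and cluster 4 in the apoptotic isogeneic library, and most T cell-like cells in cluster 7 and cluster 6. T cell-like cells had cell cycle genes at 0.71 (0.41 to 0.73), with 18 of 31 higher and 1 lower, a median that was -0.041 with clustering at a resolution of 0.5. Hspa1b was 2.97-fold (2.08 to 4.22) in T cell-like cells. In erythroid-like cells it had 58 UMIs against 0, at least 10.7-fold higher against a floor of 3 counts in the class sum, with a Poisson lower limit of 8.41-fold, but its log2 ratio was 0 after each cell was thinned to 1000 UMIs. Macrophage-like cells had cytokine genes at 0.84, with 4 of 6 higher, and Lyz2 at 4.76-fold (4.2 to 5.41), from UMIs in 17.1% of the apoptotic allogeneic and 17.4% of the apoptotic isogeneic cells. Their Cd63, a lysosomal membrane gene, was 5.68-fold (2.77 to 13.1) from UMIs in 10.98% of the apoptotic allogeneic cells, yet had a log2 ratio of -0.28 after each cell was thinned to 1000 UMIs. Mature DC-like cells had dissociation genes at 0.36, with 8 of 20 higher, and Il12b, the interleukin 12 subunit gene, at 3.58-fold (2.30 to 5.79), from UMIs in 10.98% of the apoptotic allogeneic cells. MHC class II genes were at 0.75 (4 of 6 higher) in natural killer cell-like cells and at 0.43 in non-classical monocyte-like cells, where H2-Eb1 was 2.12-fold. DCs, which are rich in these genes, were 722 of 2114 and 860 of 6263 cells in this pair of libraries, and their free RNA was not excluded here. Stromal or endothelial cells had Cxcl10 at 3.46-fold (1.95 to 6.49).

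**Figure D2:**
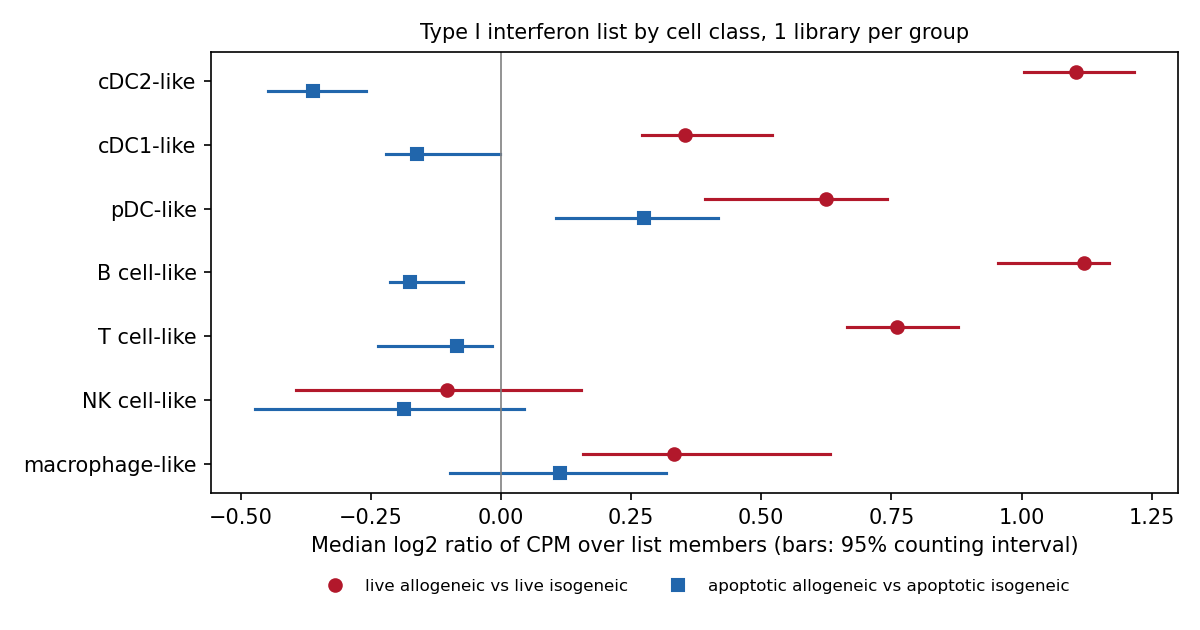
Median log2 ratio of CPM (horizontal axis) over measured type I interferon genes in 7 cell classes (vertical axis), for live allogeneic against live isogeneic (circles) and apoptotic allogeneic against apoptotic isogeneic cells (squares), with bars giving 95% counting intervals. For live cells the median is 1.10 in cDC2-like and 1.12 in B cell-like cells and -0.10 in natural killer cell-like cells.

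Infused donor cells, themselves splenic cells, were not told apart from recipient cells, and barcodes of low UMI count had been left out of the apoptotic allogeneic file alone. The strain marker gene pair that would do so was not analysed here, and Xist, expressed by female cells, was at 1685, 1322, 1243, 1482 and 1801 CPM in the saline, live allogeneic, live isogeneic, apoptotic allogeneic and apoptotic isogeneic libraries. Of 4 Y-linked genes, Kdm5d had 1 UMI in the apoptotic allogeneic and Uty 1 UMI in the live allogeneic library, and Ddx3y and Eif2s3y had 0 in all libraries.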

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

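Of the tests below, those of the low-UMI barcodes, of the mix of cDC2-like clusters, of free RNA by the library profile in live allogeneic cells and of marker medians in cycling T cell-like cells were chosen before their results were seen, and the others after. None of the differences between pairs of libraries was tested, since each group has 1 library.

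Several gene lists were picked out because the allogeneic to isogeneic median lay on opposite sides of 0 for live and for apoptotic cells, with both counting intervals away from 0. In cDC2-like cells these were type I interferon genes (1.10 live, -0.36 apoptotic), interferon-gamma genes (1.09 and -0.14) and dissociation and heat stress genes (-0.31 and 0.26). In cDC1-like cells these were type I interferon genes (0.35 and -0.16) and dissociation genes (-0.22 and 0.11). In pDC-like cells they were NF-kappaB targets (-0.38 and 0.35) and dissociation genes (-0.48 and 0.29). Barcodes under 100 UMIs, which hold mostly free RNA and enter no comparison, were picked out because their type I interferon genes lay above saline in the live allogeneic library, at a median log2 ratio of 0.55 (0.49 to 0.74). They lay at 0.012 in the live isogeneic and -0.020 in the apoptotic isogeneic library. Interferon-gamma genes in such barcodes of the live allogeneic library were at 0.63 (0.56 to 0.88).

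The first pattern weighed is that type I interferon genes such as Isg15, Irf7 and Ifit3 were higher in cDC2-like cells with live allogeneic than live isogeneic cells. Another mix of the clusters is argued against by the lower of the within-cluster medians, 0.91 (0.74 to 1.05). Free RNA is argued against by the median after subtraction of the library profile, 1.10 (1.001 to 1.21), and of the measured profile of barcodes under 100 UMIs, 1.103 (1.009 to 1.22). A shift of equal size in every class is argued against by NK cell-like cells, at -0.10 (-0.39 to 0.15), the lowest median of the classes compared. A shift of unequal size in every class stays open. Of the 10 genes highest in live allogeneic cDC2-like cells, 5 were measured in NK cell-like cells. There 4 of these lay above 0, at a median of 0.79. A response to foreign antigen was not tested and stays open, as does any other difference between the animals or libraries, since each group has 1 library.

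The second pattern is that cell cycle genes such as Pclaf and Mki67 were higher in T cell-like cells with live allogeneic cells. Doublets with B cell-, cDC1-, cDC2-, pDC-, macrophage- or erythroid-like cells, as the source of every cycling cell, are argued against by marker UMIs. Markers of each of these 6 classes were taken as a percentage of their level in that class, and the 6 percentages were added. The sum was 8.27% (7.14 to 9.42) in cycling T cell-like cells and 14.6% in the others. Most of it came from cDC2 markers, at 5.35% and 10.4%. B cell markers went the other way, at 1.51% in cycling cells and 1.37% in the others. As an average over 39 cells, the sum cannot exclude that some of them were such doublets, which stays open. Marker medians left the doublet question open, at -0.064 (-0.70 to 0.24) for B cell and -0.22 (-0.87 to 0.44) for cDC1 markers. The prediction against doublets asked for B cell, cDC1 and erythroid medians all below 1. Only 3 B cell markers, 1 cDC1 marker and 0 erythroid markers were measured, so that the erythroid median could not be taken. Doublets with other T cell-like cells, NK cell-like cells, plasma cells or the unnamed cluster 20, which cycle genes lead in part, were not among those measured and stay open. The 39 cycling cells held 824911 UMIs in all and the other 109 T cell-like cells 574057. Deeper sequencing of live allogeneic cells cannot be told apart: the median was 0.90 as the mean of 20 thinnings to 1000 UMIs per cell. Medians of single thinnings ran from 0.564 to 1.26. The lowest limit of any interval was 0.36 and the highest 1.70, from different thinnings, a range that includes the bound of 0.5. Taken singly, 14 of the 20 thinnings had an interval above that bound and 0 below it, the form of this test having been set after single thinnings were seen to differ. Another mix of T cell-like clusters cannot be told apart either. The lowest median within a cluster was -0.60 (-0.82 to -0.11), in cluster 7, and the highest 1.19 (1.03 to 1.35), in cluster 14. Cluster 14 held 21 of the 39 cycling cells. The prediction for such a mix asked for at least 1 cluster median under 0.5 and was met. This test was first read as going with a mix and was set to open after its value was seen. The reason was that 12 of the 34 cycle genes were among the genes the clusters were formed on. Division of recipient or donor T cells was not tested and stays open.

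The third pattern is that type I interferon genes such as Ifit3, Isg15 and Dhx58 were lower in cDC2-like cells with apoptotic allogeneic than apoptotic isogeneic cells. Removal of low-UMI barcodes in the apoptotic allogeneic file alone is argued against by the median at a minimum of 2000 UMIs, -0.36 (-0.43 to -0.24). That file starts at 500 UMIs, below the minimum of 1000 used for all libraries, and the higher minimum left 4.11% and 2.55% fewer cDC2-like cells in the apoptotic allogeneic and isogeneic libraries, so that few cells of low UMI count enter this median. This test had first been left open because it took away so few cDC2-like cells, and that condition, which its prediction did not hold, was dropped after the values were seen. Free RNA was measured in the apoptotic isogeneic library alone, as barcodes under 100 UMIs of the apoptotic allogeneic one were not analysed here. Free RNA of the isogeneic library is argued against by the median after its measured profile was subtracted there and the total kept, -0.31 (-0.39 to -0.22). With the total taken anew this was -0.40. Free RNA of the allogeneic library cannot be told apart, since the median of -0.37 (-0.45 to -0.27) after subtraction of library profiles rests there on no measured free RNA, and B and T cell markers in the same cells were lower in that library (-0.88 and -0.59). A shift of every class alike would not give the pDC-like median of 0.27 (0.11 to 0.42), the highest of the classes compared. With cells thinned to 1000 UMIs, however, pDC-like cells with at least 3 type I interferon UMIs were fewer in the apoptotic allogeneic library. They were 23.5% (14.1 to 35.4) there and 34.4% (26.1 to 43.6) in the apoptotic isogeneic one, with overlapping intervals. The mean of type I interferon UMIs per thinned pDC-like cell was 2.41 in the apoptotic allogeneic and 2.29 in the apoptotic isogeneic library, the same way as the median. As the measures do not all go the same way, this class does not settle the question. A biological difference between allogeneic and isogeneic apoptotic cells could also give it and stays open.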

How the results depend on the processing

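These alternatives were added after the data were seen: saline or the apoptotic isogeneic library as the reference, a library total without the library-wide genes, each cDC2-like cluster alone, and every alternative for lists in classes other than cDC2-like cells. No paired analysis was possible because each group has 1 library. The mean CPM per cell gave no gene spread, and pDC-like cells were too few for the live spread with at most 5% mitochondrial UMIs or with thinned cells. Values given as moved left the 95% counting interval of the reported value or, for the gene spread, the range of its thinnings and Poisson draws. The cause of each was not tested unless stated.

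Type I interferon genes in cDC2-like cells stayed higher with live allogeneic than live isogeneic cells under every alternative run, from 0.65 to 1.36 as a median log2 ratio, as did interferon-gamma genes, from 0.54 to 1.37. Type I interferon genes stayed lower with apoptotic allogeneic than apoptotic isogeneic cells, from -0.47 to -0.19. The maturation list had no stable direction for live cells, from -0.33 to 0.59. Over the 6 list medians, 101 of 123 alternative values lay within the counting interval, 21 moved and 1 reversed. Over 12 medians against saline, 174 of 204 did, 28 moved and 2 reversed. For the gene spread 58 of 103 did, and 45 moved. For 178 named genes 2487 of 2974 did, 473 moved and 14 reversed. For 47 list medians in other classes 615 of 733 did, 115 moved and 3 reversed. For the cDC2-like share, 27 of 35 values over DCs and 21 of 35 over all cells did.

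Pseudocounts rescale every log2 ratio by construction. With 1 CPM the live gene spread was 0.97 (cDC2-like), 0.89 (cDC1-like) and 0.92 (pDC-like) and the apoptotic one 0.77, 0.79 and 0.78. Live type I interferon and interferon-gamma medians were 1.36 and 1.37, those of live allogeneic cells against saline 1.33 and 1.60, and the correlation of live and apoptotic ratios -0.082. With 50 CPM the live spread was 0.53, 0.47 and 0.49 and the apoptotic one 0.39, 0.40 and 0.41. The live medians were 0.65 and 0.54, the apoptotic type I median -0.19, those of live allogeneic cells against saline 0.69 and 0.61, that of apoptotic allogeneic type I genes against saline -0.17 and the correlation -0.15.

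A minimum of 100 UMIs per gene leaves genes of less counting error. The live spread was then 0.77, 0.57 and 0.63 and the apoptotic one 0.40, 0.42 and 0.43, the apoptotic type I interferon median -0.24 and the interferon-gamma median of apoptotic isogeneic cells against saline -0.21. Without a minimum, the live spread was 0.81 in cDC1-like and 0.85 in pDC-like cells and the apoptotic one 0.74, 0.75 and 0.75. The interferon-gamma median was then 0.64 for live cells and 0.84 for live allogeneic cells against saline.

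Thinning each cell to 1000 UMIs leaves fewer counts. The live spread was then 1.11 in cDC2-like and 0.98 in cDC1-like cells and the apoptotic one 0.81, 0.80 and 0.82. Against saline, live allogeneic medians were 1.25 for type I interferon, 0.97 for interferon-gamma and -0.25 for maturation genes. Live isogeneic interferon-gamma genes reversed to -0.045, with maturation genes at -0.37. The apoptotic allogeneic interferon-gamma median was -0.36. Apoptotic isogeneic type I genes reversed to -0.008, with interferon-gamma genes at -0.15 and maturation genes at -0.22. Hist1h2ab in cDC1-like (-0.51), Gaa in erythroid-like (0.36) and Cd63 in macrophage-like cells (-0.28), apoptotic allogeneic against isogeneic, reversed, as did the cell cycle list in erythroid-like cells for live cells (-0.064).

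With at least 2000 UMIs per barcode, the live cDC2-like spread was 0.86 and the maturation median of live isogeneic cells against saline 0.039. The cDC2-like share of all cells was 17.5% in the saline, 10.5% in the live isogeneic and 11.1% in the apoptotic isogeneic library, and of DCs 44.5% in the live isogeneic one. With at most 5% mitochondrial UMIs, the live spread was 0.94 in cDC2-like and 0.82 in cDC1-like cells and the apoptotic one 0.72, 0.72 and 0.75, from fewer cells. Ly6d in non-classical monocyte-like cells reversed to 2.41 for apoptotic cells. The cDC2-like share of all cells was 21.3%, 12.6%, 11.2%, 20.2% and 10.4% in the saline, live allogeneic, live isogeneic, apoptotic allogeneic and apoptotic isogeneic libraries, and of DCs 48.5% in the saline and 53.7% in the apoptotic isogeneic one. Without doublet removal, the maturation median of live isogeneic cells against saline was 0.055.

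At a clustering resolution of 2, only the cluster led by Cd209a kept the cDC2-like name, so that fewer cells entered. The cDC2-like spread was 0.94 for live and 0.67 for apoptotic cells. The live maturation median was 0.32, and apoptotic medians were -0.47 (type I interferon), -0.52 (interferon-gamma) and -0.32 (maturation). Against saline these lists were at 1.46, 1.57 and 0.31 with live allogeneic, 0.24, 0.36 and 0.17 with live isogeneic and -0.13, -0.42 and -0.28 with apoptotic allogeneic cells, and the type I list at 0.27 with apoptotic isogeneic cells. Tmod2, live allogeneic against saline, reversed to 0.029. The share of DCs and of all cells was 16.6% and 3.7% in the saline, 23.5% and 3.88% in the live allogeneic, 16.7% and 2.8% in the live isogeneic, 18.9% and 4.21% in the apoptotic allogeneic and 22.2% and 1.95% in the apoptotic isogeneic library. At a resolution of 0.5, the share of all cells was 10.6% in the live isogeneic library, and the cell cycle median of T cell-like cells for apoptotic cells reversed to -0.041. With genes centred per library, the live type I interferon median was 0.99 and the maturation median of live isogeneic cells against saline 0.041.

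After subtraction of free RNA, the live spread was 0.88, 0.78 and 0.84 and the apoptotic one 0.68, 0.69 and 0.71. The correlation was -0.13, and the type I interferon median of macrophage-like cells for live cells reversed to -0.24. Without the library-wide genes in the total, the live pDC-like spread was 0.80 and the type I median of live isogeneic cells against saline 0.061.

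In cluster 1 alone, live medians were 1.24 (type I interferon), 1.27 (interferon-gamma) and 0.58 (maturation), and apoptotic ones -0.49 (interferon-gamma) and -0.31 (maturation). In cluster 12 alone, live medians were 0.91 (type I interferon) and -0.33 (maturation), and the apoptotic ones -0.26 (type I interferon) and, reversed, 0.10 (interferon-gamma). With saline as the reference, the live allogeneic spread was 0.86 in cDC2-like and 0.78 in cDC1-like cells, and reversed genes were AY036118 (0.10) and Zfp36 (0.43) with live allogeneic and Gm10076 (-0.66), Psme2b (-0.28), Wdr89 (0.21) and Ifi27l2a (0.044) with apoptotic allogeneic cells. With the apoptotic isogeneic library as the reference, the live allogeneic type I interferon median was 0.98, and Gm10076 (1.22), AY036118 (0.29) and Zfp36 (0.31) reversed.

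Depth limits what these libraries can show. In simulated cDC2-like cells, live allogeneic against live isogeneic, 12.6% of the 8846 genes without a change passed 1.5-fold. These were Poisson counts that held no differences between cells or animals.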

Other observations

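The genes compared within cycling T cell-like cells were chosen after the data were seen. In the live allogeneic library, 39 of 148 T cell-like cells held at least 10 UMIs of cell cycle genes. This cut was on counts before thinning, so that cells of more UMIs pass it more easily. The 39 cells held 824911 UMIs in all and the other 109 cells 574057. Gzmb, which encodes a killing enzyme of activated T cells, was at 44.9 CPM (31.6 to 61.8) in these and at 5.2 CPM (1.1 to 15.3) in the other 109. Cd4, the helper T cell coreceptor gene, was at 32.7 CPM (21.6 to 47.6) and 87.1 CPM (64.6 to 114.8), and Cd8b1, the killer T cell coreceptor gene, at 337.0 and 451.2 CPM. Foxp3, the regulatory T cell factor gene, was at 19.4 CPM (11.1 to 31.5) and 40.1 CPM (25.4 to 60.1), with overlapping intervals. In the live isogeneic library, 49 T cell-like cells held as many cycle UMIs. Gzmb was at 13.2 CPM (4.3 to 30.7), from 5 UMIs, in those and 2.7 CPM (1.0 to 6.0) in the others, and Cd4 at 150 CPM in those. Foxp3 was at 52.6 CPM (32.2 to 81.3) in those and 17.9 CPM in the others, the other way round. Gzmb was at 13.1 CPM (2.7 to 38.4), from 3 UMIs, in cycling and 2.2 CPM (1.0 to 4.4) in other cells of the apoptotic isogeneic library. It was at 21.2 CPM, from 2 UMIs, and 0 CPM in the apoptotic allogeneic one, and at 0 CPM in both with saline. Outside the live allogeneic library, higher Gzmb in cycling cells thus rests on few UMIs, with overlapping intervals. Whether it is particular to the live allogeneic library stays open. In the apoptotic isogeneic library Cd4 was at 39.4 CPM (18.0 to 74.8) in 26 cycling T cell-like cells and 96.2 CPM (86.3 to 107.0) in the others, so that lower Cd4 is not particular to live allogeneic cells. It was at 31.8 CPM (6.5 to 92.8), from 3 UMIs in 8 cells, and 101.6 CPM (82.6 to 123.7) in the apoptotic allogeneic library, and at 111.5 CPM (30.4 to 285.4) in 5 cycling cells and 100.7 CPM in the others with saline.

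With each cell thinned to 1000 UMIs, the share of T cell-like cells with at least 3 cell cycle UMIs was 9.0% in the saline, 22.97% (16.5 to 30.6) in the live allogeneic, 12.7% (10.0 to 15.8) in the live isogeneic, 5.9% in the apoptotic allogeneic and 6.3% in the apoptotic isogeneic library. Unthinned, the shares were 50.2%, 79.1%, 77.6%, 66.1% and 39.3%. Macrophage-like cells had 29.7% (15.9 to 47.0) with live allogeneic and 11.1% (4.6 to 21.6) with live isogeneic cells after thinning, and 64.9% and 38.1% before it. For NK cell-like cells these were 28.6% (14.6 to 46.3) and 13.6% (8.3 to 20.7) after thinning, and 80.0% and 72.0% before it. The intervals after thinning overlap in macrophage-like and in NK cell-like cells.

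Erythroid-like cells were 8.86% of the cells in the live isogeneic library, at a median of 3955 UMIs, and between 1.65% and 5.87% in the other libraries, at medians of 23004 to 41387.5 UMIs. Of the 10 pairs of libraries, 8 shared more cell barcodes than given by chance. The most were 8 for live and apoptotic isogeneic cells, against 3.39 by chance, while live allogeneic and live isogeneic cells shared 3 against 0.642, and live allogeneic cells shared 0 with saline and with apoptotic isogeneic cells.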
